A study of Mus musculus with 6 samples.

How the data were processed

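Gene expression was measured by RNA sequencing in 6 libraries, 1 per mouse, from 3 old and 3 young C57BL/6 mice. Per the labels, each library came from lung endothelial cells after acid injury. The labels give no ages in months, no sex, no time after injury and no uninjured samples. The labels' protocols speak of tissue that was taken out and homogenized and of an Illumina TruSeq RNA kit. They name no cell isolation step, and whether the kit kept strand is not given in the sources used here.

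The authors deposited 1 table per library, with gene identifiers and FPKM values (fragments scaled to gene length and library size), and per the file headers no counts. Per the submitters' processing notes, CASAVA 1.7, Bowtie 0.12.2 and the mouse genome build mm8 were involved, with no role stated for any of them. The counter and the annotation are not given in the sources used here. Gene lengths implied by the FPKM values equalled the merged exon length in GENCODE mouse release 21, an annotation of the later build GRCm38, for 78.85% of the genes kept. The stated build and the lengths therefore point to different annotations, and the coordinates given here are those of GENCODE M21 on GRCm38.

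All 6 deposited FPKM tables were damaged as received. Each had 24720 gene rows, of which the first 2884 were intact. From there on, characters inside identifiers and values were altered, rows were split or fused, and some numbers had lost their decimal point. Identifiers were malformed in 3880 rows, and 593 well-formed identifiers had no symbol in the gene name table. Between 1528 and 2590 value cells per library held text in place of a number, and between 177 and 2328 were empty. In the table of young mouse 3, the 18 other columns held cells in 432 rows. Such columns were not used for any library.

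Silently altered digits were searched for with a property of the intact values. Each FPKM value was a whole number of fragments divided by the gene length and the library total, up to the constant of the unit. A single whole-base length per gene had to give whole fragments in all 6 libraries, within a tolerance of 1e-06 fragments plus a relative 3e-13. All 2884 intact first rows passed. Of 19063 rows with a known identifier and 6 readable numbers, 26 failed. No value was repaired. The 19037 genes kept had a known, well-formed, unique identifier and 6 values that passed, and 5683 rows (22.99%) were left out. Of 485 members of the fixed lists, 333 were intact and above the filter on mean FPKM described here, and a list's count covers those alone. An altered identifier that happened to give another valid identifier would not be seen by the test on values. The share of genes with the M21 exon length was 79.04% among the intact first rows and 78.82% among later rows.

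The same property gave the depth of each library. Implied totals were 13220833, 11381122 and 17931463 fragments for old mice 1, 2 and 3, and 17723926, 15521113 and 14903398 fragments for young mice 1, 2 and 3. A scaling factor inside these totals cannot be ruled out. In a gene of 2 kb, 1 fragment was worth 0.0279 to 0.0439 FPKM. A gene at 0 in every library of a group was set against a floor of 3 fragments per library, which covers counting error only.

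Rows sharing a symbol were summed, which left 19033 genes. The 10010 genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, no covariates, two-sided). FPKM values were used as the authors deposited them, without rescaling. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Log2 fold changes are old minus young on the log2(FPKM + 1) scale, which understates changes of genes with low FPKM. Folds quoted are 2 to the power of these values, except a fold against a floor, which divides a group's mean FPKM by that floor. The labels name separate mice, so the p-values measure the spread between mice.

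Of 41 gene lists fixed before the data were examined, the 39 with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, against all other tested genes. The mitochondrially encoded list had 1 tested member and the sex-linked list 0, so neither entered camera. Camera with an estimated correlation and the rotation test fry were run beside it. The 333 tested members of all lists were also adjusted over the lists' union alone, and each list's members over the list alone.

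The genes named were chosen by a rule fixed before the data were examined. It took the 12 largest changes per direction among genes past the threshold whose old and young values did not overlap, without predicted, clone-named and small RNA symbols. From each list it took up to 4 members past the threshold, or up to 2 of the highest mean FPKM where none passed. It always included Nrp1, Epas1, Procr, Il1a, Timp1, Pecam1, Cdh5, Cdkn1a and Cdkn2a. The rule gave 100 genes. Procr and Cdkn2a had no intact row and are not analysed here. Genes named outside the rule are introduced as chosen after their values were seen.

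Alternatives changed the pseudocount (0.1 or 0.01), the filter (none, or a mean FPKM of 5), the scaling (median ratios or quantiles), the variance prior, the sample weights, a block on the mouse number, and left out each library in turn. The analyses of genes with the M21 length alone, and of the old libraries against young mouse 1 alone, were added after the data had been examined. The limma fit and its threshold were tested on simulated fragments drawn with the means, spreads (kept within bounds) and totals of the 6 libraries. Each gene was drawn on its own, so spread that genes share across libraries was absent and its effect on false calls was not measured. Camera, fry and the check of values were not simulated. In that simulation of old against young, with 9965 genes tested, 34 of 91 genes changed 4-fold and 70 of 94 changed 16-fold were called, each in the right direction. A further 9 unchanged genes were called, and 0 genes were called when no change was simulated. The checks of values were run in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.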

Results

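RNA was sequenced from lungs of old and young mice injured with acid, in libraries labelled as vascular endothelial cells, the cells that line blood vessels. There were 3 libraries from old and 3 from young C57BL/6 mice, each from a separate mouse. Implied depth ran from 11381122 to 17931463 fragments per library. The design has 1 comparison, old against young after injury, which asks how gene expression in these cells differed with age. No uninjured libraries were analysed here, so no response to injury was measured.

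Genes that mark endothelial cells were lower in the old libraries, and genes of fibroblasts and mesothelium were higher. Pecam1, an adhesion molecule at endothelial cell junctions, was at 5.88 ± 2.09 FPKM (SD, n = 3) in old and 77.2 ± 35.7 FPKM (SD, n = 3) in young mice. Cdh5, the endothelial cadherin, was at 6.06 ± 3.79 against 66.5 ± 7.98 FPKM (SD, n = 3 each). In the other direction, the collagen gene Col1a1 was at 216 ± 62.9 FPKM in old and 11.2 ± 1.82 FPKM in young mice, and Mfap4, a gene of matrix microfibrils, at 378 ± 168 against 3.73 ± 1.64 FPKM (SD, n = 3 each). The differences amounted to a log2 fold change of -3.44 ± 0.43 (SE, limma adjusted p = 0.0115) for Pecam1, -3.45 ± 0.49 (adjusted p = 0.0176) for Cdh5, 4.13 ± 0.28 (adjusted p = 0.00269) for Col1a1 and 6.29 ± 0.39 (adjusted p = 0.00269) for Mfap4.

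Across the 10010 genes tested, limma called 498, of which 295 were higher and 203 lower in old mice. A change of at least 4-fold on the log scale was seen for 277 of them, 179 higher and 98 lower. The old and young values overlapped for none of the 498, which a call with so few mice nearly requires. Of all tested genes, 31.1% did not overlap, against 10% expected by chance for 3 against 3. Genes that vary together can give a share far from that expectation, and the share was not computed for other splits. The count was 84 without old mouse 3 (72 higher, 12 lower), 134 without old mouse 2 (96 and 38) and 192 without old mouse 1 (153 and 39). It was 196 without young mouse 3 (107 and 89), 262 without young mouse 1 (144 and 118) and 395 without young mouse 2 (266 and 129). Libraries correlated at 0.905 to 0.921 (Pearson's r across genes) within the old group and at 0.844 to 0.917 within the young group. Young mouse 1 correlated at 0.859 and 0.844 with young mice 2 and 3, and these at 0.917 with each other. Between the groups, r ran from 0.741 to 0.86. Young mouse 2 was thus as close to old mouse 3 (0.86) as to young mouse 1 (0.859). Young mice 2 and 3 were rich in neutrophil transcripts, and against young mouse 1 alone limma called 413 genes, 195 of them among the 498.

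**Figure D1:**
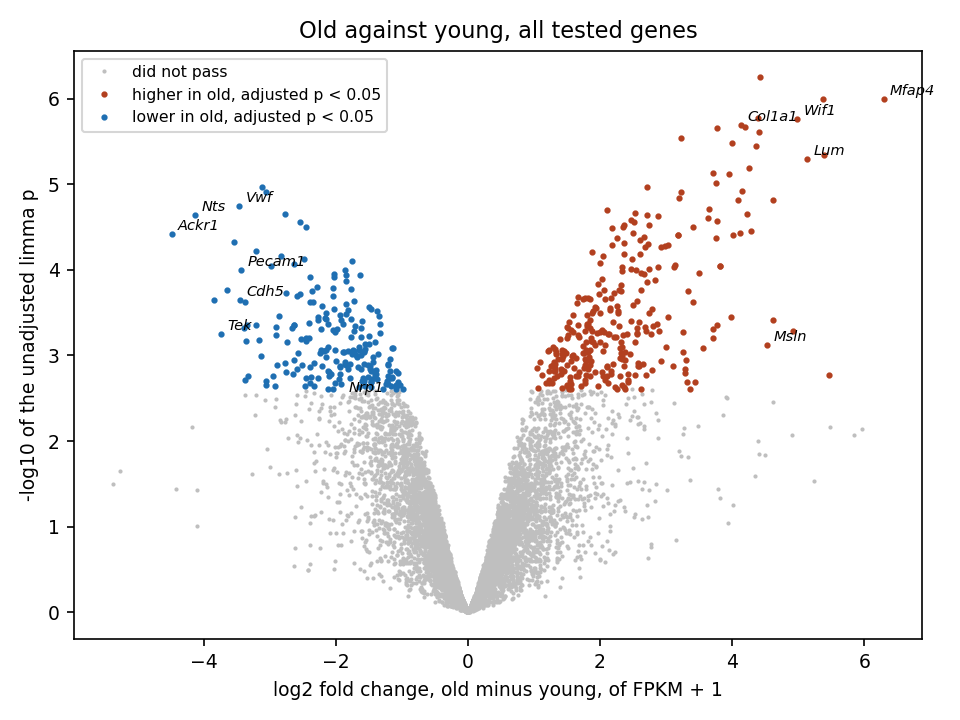
Log2 fold change of FPKM + 1 (old minus young, x axis) against -log10 of the unadjusted limma p (y axis), 1 point per tested gene (10010 genes, 3 old and 3 young libraries). Red points are the 295 genes higher in old and blue points the 203 lower in old at an adjusted p under 0.05, and Nrp1 lies just short of the threshold.

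In the pan-endothelial list, 10 of 15 tested genes fell, 0 rose and 5 did not pass. Adjusted over the list alone, 15 of 15 were lower in old mice. The median log2 fold change was -3.14, and -2.35 without old mouse 1. Tek, the angiopoietin receptor, fell by 3.74 ± 0.62 (SE) on the log2 scale and Mmrn2, a protein of the endothelial matrix, fell by 3.64 ± 0.50. The call for Tek ended in 5 of 6 fits that left out 1 library and with the block (highest adjusted p 0.0877). The list differed from other genes by camera (adjusted p = 1.5e-11, or adjusted p = 0.4825 with an estimated correlation). The call for Pecam1 ended with a block on the mouse number (adjusted p = 0.0605, range over its alternatives 0.00685 to 0.0605), and that for Cdh5 with the block, without old mouse 3 and against young mouse 1 alone (range 0.00928 to 0.0707).

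Of the arterial genes, 4 of 7 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00352, or adjusted p = 0.4825 with an estimated correlation). Gja5, a gap junction protein of arteries, fell by 2.77 ± 0.27 on the log2 scale, Bmx by 1.85 ± 0.24 and Efnb2 by 1.68 ± 0.31. Dkk2, a secreted Wnt modulator placed in that list, rose by 2.88 ± 0.29. Of the venous genes, 2 of 6 fell (4 adjusted over the list alone; camera adjusted p = 0.00352, or adjusted p = 0.4825 with an estimated correlation). Ackr1, a chemokine-binding receptor of venules, was at 2.23 ± 2.20 FPKM in old and 63.0 ± 16.6 FPKM in young mice (SD, n = 3 each), and fell by 4.48 ± 0.48 on the log2 scale. Ephb4 fell by 2.33 ± 0.44. The arterial call ended with a filter at a mean FPKM of 5 (adjusted p = 0.0888).

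The general capillary, aerocyte capillary and lymphatic lists did not pass by camera (adjusted p = 0.0839, 0.089 and 0.262). The first was called lower in 4 of 18 settings, the second in 3 and the third in 0, and the rotation test fry called the first (adjusted p = 0.0386). Of the general capillary genes, 1 of 5 fell (3 adjusted over the list alone), which was Cd93 at a log2 fold change of -2.46 ± 0.26. Of the aerocyte capillary genes, 1 of 5 fell (2 adjusted over the list alone), which was the endothelin receptor Ednrb at -3.38 ± 0.49. In the lymphatic list, 0 of 5 fell and Fxyd6, a regulator of the sodium pump, rose by 2.68 ± 0.30, while 3 were lower and 1 higher adjusted over the list alone.

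Large falls among genes of no fixed list were seen in Nts, which encodes neurotensin, at -4.13 ± 0.41 on the log2 scale, the junction gene Jam2 at -3.85 ± 0.55, Lrg1 at -3.54 ± 0.39 and Exoc3l2 at -3.38 ± 0.69. The call for Exoc3l2 ended under most alternatives that left out 1 library, with the block, at lower pseudocounts and without a filter, and that for Jam2 with the block and without old mouse 3. Lrg1, a secreted glycoprotein, stayed among the more abundant of these, at 40.8 to 97.8 FPKM in old and 519 to 855 FPKM in young libraries.

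Fibroblast genes were higher in the old libraries, with 7 of 8 tested members past the threshold, also when adjusted over the list alone, and a median log2 fold change of 4.12. Lum, a collagen-binding proteoglycan, was at 559 ± 208 FPKM in old and 15.2 ± 6.93 FPKM in young mice (SD, n = 3 each). Col1a2 rose by 4.26 ± 0.35 (SE) on the log2 scale. The list was called by camera (adjusted p = 5.14e-10, or adjusted p = 0.4825 with an estimated correlation). Of the mesothelial genes, which mark the lining of the lung surface, 3 of 5 rose (4 adjusted over the list alone; camera adjusted p = 0.00055, or adjusted p = 0.4825 with an estimated correlation). These were Msln at 4.53 ± 0.79, the urothelial and mesothelial membrane protein Upk3b at 3.72 ± 0.60 and the keratin Krt19 at 3.51 ± 0.45. The call for Msln ended without old mouse 2, old mouse 3, young mouse 1 or young mouse 3, without a filter, and against young mouse 1 alone (adjusted p 0.0231 to 0.101 over its alternatives).

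In the TGF-beta and matrix list, 5 of 15 genes rose, 0 fell and 10 did not pass (9 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00665, or adjusted p = 0.4825 with an estimated correlation). Col5a1, a fibrillar collagen, rose by 4.19 ± 0.29 on the log2 scale, Postn, which encodes periostin, by 4.0025 ± 0.30, Ltbp2 by 2.72 ± 0.24 and the collagen cross-linking enzyme Lox by 2.46 ± 0.39. The camera call ended with a filter at a mean FPKM of 5 (adjusted p = 0.103). Complement genes were also higher, with 3 of 5 past the threshold (4 adjusted over the list alone; camera adjusted p = 0.00297, or adjusted p = 0.4825 with an estimated correlation). Serping1, the C1 inhibitor, rose by 3.01 ± 0.53, C3 by 2.26 ± 0.49 and C4b by 2.11 ± 0.41. Leaving out 1 library ended the call in 5 of 6 fits for Serping1 and C3 and in 6 of 6 for C4b, and that for C3 (adjusted p = 0.0499) also ended with both scalings.

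Other genes with the largest rises were Mfap5 at 5.39 ± 0.42 on the log2 scale, Cyp26a1, which breaks down retinoic acid, at 5.38 ± 0.33, the Wnt inhibitor Wif1 at 4.99 ± 0.34, Itgbl1 at 4.42 ± 0.25 and Serpinf1 at 4.41 ± 0.31. Wif1 was at 20.8 to 49.5 FPKM in the old libraries and at 0.186, 0 and 0.028 FPKM in young mice 1, 2 and 3. The mast cell protease Mcpt2 was listed at 0 in all 3 young libraries and at 14.6 to 47.9 FPKM in the old. The mean of the old libraries, 27 FPKM, was 130-fold the highest floor of 3 fragments in a young library (0.207 FPKM). Mpo, the granule peroxidase of myeloid cells, was at 421, 15.5 and 68.9 FPKM in old mice 1, 2 and 3 and at 0 to 1.56 FPKM in young mice. It rose by 5.47 ± 1.10 (by 4.25 without old mouse 1 and 6.59 without old mouse 2), Cst7 by 4.62 ± 0.72 and the T cell receptor segment Trbd1, which held 31 fragments in all 6 libraries, by 4.92 ± 0.81. These calls each ended under several alternatives, among them the block and leaving out old mouse 1 or old mouse 3 (highest adjusted p 0.116 for Mpo, 0.126 for Cst7 and 0.0832 for Trbd1). Mcpt2 and Trbd1 have near-identical relatives, so their values are uncertain. Trbd1 also spans only 41533201 to 41533212 on chromosome 6, so each fragment counted there gave a large FPKM value.

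Epithelial genes were higher in old mice for the airway list, in which 2 of 5 rose (3 adjusted over the list alone; camera adjusted p = 0.00688, or adjusted p = 0.516 with an estimated correlation). The keratin Krt8 was at 509 ± 50.7 FPKM in old and 69.8 ± 29.3 FPKM in young mice, and Epcam at 85.5 ± 14.3 against 11.1 ± 7.90 FPKM (SD, n = 3 each). The airway call ended among genes with the M21 length alone (adjusted p = 0.305). Of the alveolar type 1 genes, 1 of 4 rose (2 adjusted over the list alone), which was Pdpn at 2.31 ± 0.41 on the log2 scale. Camera did not call the list (adjusted p = 0.0561) but called it higher in 5 of 17 settings, among them the block (adjusted p = 0.0128) and young mouse 1 alone. These settings use the preset correlation, while the estimate was 0.718, with an adjusted p of 0.607 for all 6 libraries. Of the alveolar type 2 genes, 0 of 4 passed (camera adjusted p = 0.595), with Sftpd at 51.0 to 60.6 FPKM in old and 3.83 to 55.4 FPKM in young libraries. The cardiac muscle list was not called by camera (adjusted p = 0.312), and 1 of its 4 genes, the myosin light chain Myl7, rose by 3.72 ± 0.63. In the smooth muscle and pericyte list 0 of 7 passed (camera adjusted p = 0.414), and Acta2 stood at 810 FPKM in young mouse 2 against 24.4 and 37.8 FPKM in young mice 1 and 3. The estimated correlation among the list's members was 0.938, which gave camera an adjusted p of 0.808 for all 6 libraries. At the preset correlation of 0.01 and without young mouse 2, that list was called higher in old mice (adjusted p = 2.08e-05). Against young mouse 1 alone, it (adjusted p = 0.00141) and the alveolar type 2 list (adjusted p = 0.00238) were both called higher.

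**Figure D2:**
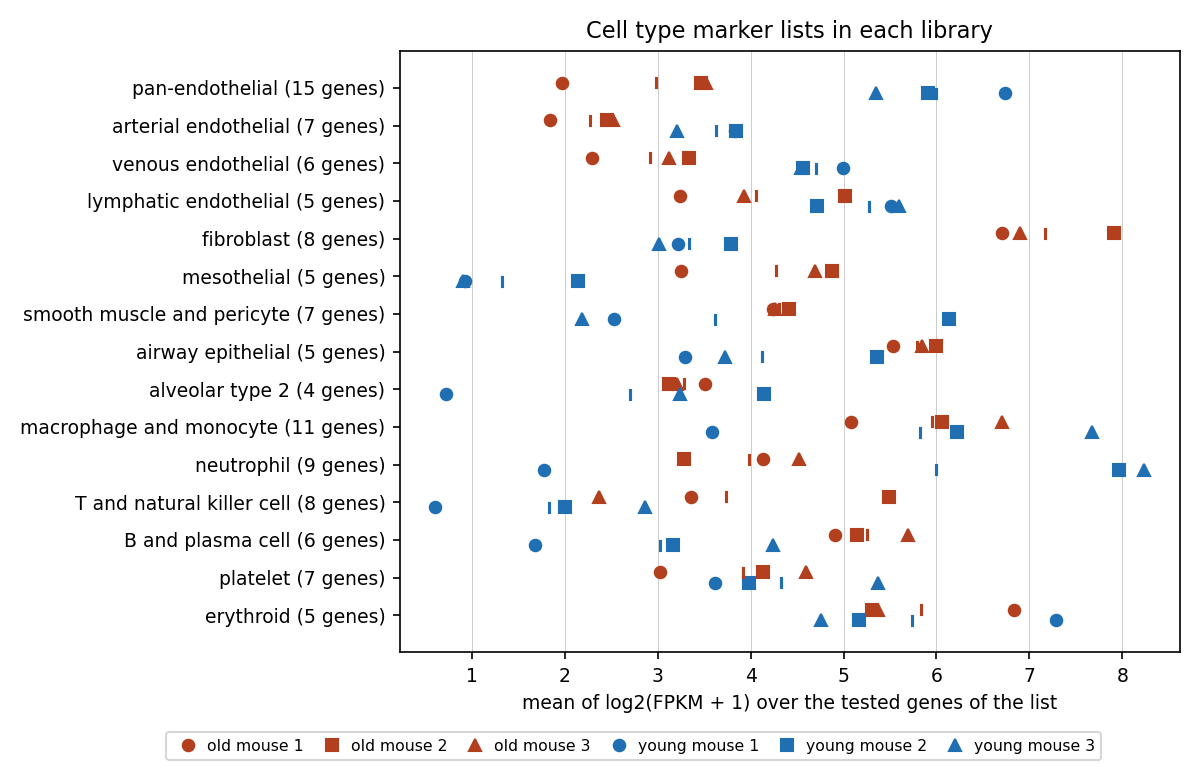
Mean of log2(FPKM + 1) over the tested genes of 15 cell type lists (x axis, lists on the y axis), 1 symbol per library (red old, blue young, 3 mice each) and a short bar at each group mean. The pan-endothelial means lie between 1.97 and 3.52 in old and between 5.35 and 6.73 in young mice, and the neutrophil mean of young mouse 1 is 1.77 against 7.97 and 8.24 in young mice 2 and 3.

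Leukocyte lists differed between libraries within each group as well as between groups. In the T and natural killer cell list, 0 of 8 genes passed, though camera called it higher in old mice (adjusted p = 0.0189, or adjusted p = 0.62 with an estimated correlation). That call ended with a filter at a mean FPKM of 5, without old mouse 2, without young mouse 1 and among genes with the M21 length. The granzyme gene Gzma was at 1385 FPKM in old mouse 2 and at 1.29 to 23.5 FPKM in the other 5 libraries. In the B and plasma cell list 0 of 6 passed (4 higher adjusted over the list alone; camera adjusted p = 0.00342, or adjusted p = 0.516 with an estimated correlation), with the kappa light chain Igkc at 1415 to 3649 FPKM in old and 10.2 to 358 FPKM in young libraries. The neutrophil list was not called by camera (adjusted p = 0.089), with 0 of 9 genes past the threshold, and its lower median rested on young mice 2 and 3. Without young mouse 1 it was called lower in old mice (median log2 fold change -4.29, adjusted p = 5.98e-11), and against young mouse 1 alone higher (median 2.58, adjusted p = 0.000576). It was also called lower with array weights (adjusted p = 0.00268) and with the block (adjusted p = 0.0311). These calls use the preset correlation of 0.01, while the estimate among its members was 0.958, which gave an adjusted p of 0.703 for all 6 libraries. S100a9, an abundant neutrophil protein, was at 11690 and 12540 FPKM in young mice 2 and 3, at 27.1 FPKM in young mouse 1 and at 182 to 516 FPKM in old mice. The macrophage and monocyte list (0 of 11, adjusted p = 0.918), the platelet list (0 of 7, adjusted p = 0.424), the erythroid list (0 of 5, adjusted p = 0.918) and the MHC class II list (0 of 4, adjusted p = 0.0561) did not pass by camera. The MHC class II list had a median of 2.2 and was called higher in old mice in 6 of 17 settings, among them the block (adjusted p = 0.0086) and without young mouse 3 (adjusted p = 0.000966). The settings given here for the MHC class II, macrophage and erythroid lists use the preset correlation. The estimates were 0.896, 0.687 and 0.915, and gave camera adjusted p = 0.607, 0.963 and 0.963 for all 6 libraries. The macrophage and monocyte list was called lower in old mice without young mouse 1 (median -0.996, adjusted p = 0.0171) and higher against young mouse 1 alone (median 3, adjusted p = 0.000576). The erythroid list was called lower against young mouse 1 alone (median -1.33, adjusted p = 0.0303).

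Neuropilin 1 (Nrp1), a coreceptor for vascular growth factors and semaphorins, and Epas1, which encodes the hypoxia-inducible factor HIF2A, head a list on their axis. Nrp1 (chromosome 8, 128358604 to 128503363 in GRCm38) was at 20.6 ± 7.67 FPKM in old and 81.0 ± 37.6 FPKM in young mice (SD, n = 3 each), with a log2 fold change of -1.91 ± 0.43 (SE), and did not pass (limma adjusted p = 0.0541, range over its alternatives 0.041 to 0.146). Epas1 (chromosome 17, 86753700 to 86833410) was at 7.45 ± 1.62 against 42.0 ± 22.5 FPKM (SD, n = 3 each) and fell by 2.24 ± 0.41 (limma adjusted p = 0.0313, range over its alternatives 0.0231 to 0.0983). Its call ended without a filter, with the block, without any 1 of the old mice or young mouse 1, and against young mouse 1 alone. Of the 10 list members tested, 4 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0128, or adjusted p = 0.4825 with an estimated correlation). The semaphorin receptor genes Nrp2 and Plxnd1 fell by 2.15 ± 0.32 and 2.58 ± 0.47, and the ligand gene Sema3f by 2.74 ± 0.47. In the same libraries the pan-endothelial median was -3.14. The list's call ended among genes with the M21 length (adjusted p = 0.237).

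**Figure D3:**
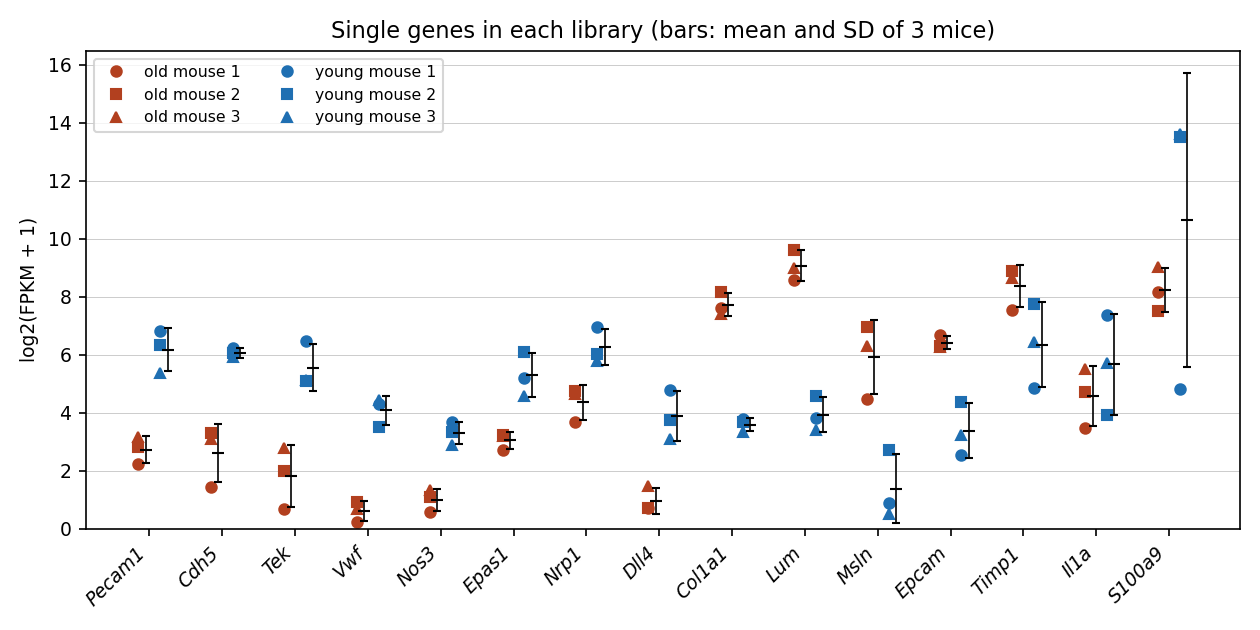
Log2(FPKM + 1) of 15 genes (y axis) in each library (red old, blue young, 1 symbol per mouse), with bars for the mean and SD of 3 mice. Pecam1 and Cdh5 lie lower in all 3 old libraries and Col1a1 and Lum higher, while Il1a overlaps between the groups.

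Of the Notch genes, 2 of 9 fell (6 adjusted over the list alone; camera adjusted p = 0.00245, or adjusted p = 0.4825 with an estimated correlation). The Notch ligand Dll4 fell by 2.91 ± 0.47 on the log2 scale and Notch4 by 1.75 ± 0.32. The list median was -1.12, against -3.14 for the pan-endothelial list in the same libraries. With pseudocounts of 0.1 and 0.01 the Notch median was -2.01 and -2.27, against -3.36 and -3.38, so the gap depends on the pseudocount. The hypoxia target list was not called by camera (0 of 12, adjusted p = 0.0848), and was called lower in 2 of 18 settings. Camera called neither the anticoagulant list (adjusted p = 0.619) nor the procoagulant list (adjusted p = 0.326), and each had members in both directions. The procoagulant list was called by fry (adjusted p = 0.0386), and lower by camera with a filter at a mean FPKM of 5 (adjusted p = 0.0435). Among the 6 anticoagulant genes, Nos3, the endothelial nitric oxide synthase, fell by 2.29 ± 0.31 and the prostacyclin synthase Ptgis rose by 3.30 ± 0.62. Among the 8 procoagulant genes, Vwf and Selp, which encode von Willebrand factor and P-selectin, fell by 3.46 ± 0.33 and 3.21 ± 0.37, and the tissue factor gene F3 rose by 2.38 ± 0.43. The calls for Ptgis and F3 each ended in 5 of 6 fits that left out 1 library, for Nos3 in 2, for Selp in 1 and for Vwf in 0.

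Of the leukocyte adhesion and cytokine genes, 1 of 14 fell, which was Sele, E-selectin, at -3.40 ± 0.55 on the log2 scale (camera adjusted p = 0.424). Il1a was at 10.08, 25.15 and 44.95 FPKM in old mice 1, 2 and 3 and at 165, 14.1 and 51.7 FPKM in young mice 1, 2 and 3, and did not pass (adjusted p = 0.495). Timp1, an inhibitor of matrix proteases, was at 353 ± 150 FPKM in old and 110 ± 96.2 FPKM in young mice (SD, n = 3 each) and did not pass (limma adjusted p = 0.169). In the senescence-associated list 0 of 8 passed (adjusted p = 0.424), among them Cdkn1a, at 158 ± 48.4 FPKM in old and 263 ± 130 FPKM in young mice (SD, n = 3 each; limma adjusted p = 0.42).

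Besides the T and natural killer cell list and the B and plasma cell list, camera called 2 more lists in which 0 genes passed. The cell cycle list lay higher in old mice (22 genes, median log2 fold change 0.82, adjusted p = 0.00269, or adjusted p = 0.683 with an estimated correlation), with Ccnb2 at 18.0 to 65.4 FPKM in old and 7.02 to 14.0 FPKM in young libraries. That call ended without old mouse 1 (median 0.183, adjusted p = 0.171) and against young mouse 1 alone (adjusted p = 0.062). The ribosomal protein list also lay higher (18 genes, median 0.68, adjusted p = 0.000643, or adjusted p = 0.622 with an estimated correlation), by a median of 0.358 without old mouse 1 (adjusted p = 0.0175). Across all tested genes, longer genes tended to lower values in old mice (Spearman rho = -0.28). Gene length was not tested for the ribosomal protein list.

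Camera did not call the remaining lists. These were the interferon-stimulated (0 of 11 past the threshold, adjusted p = 0.101), angiocrine (1 of 9, adjusted p = 0.918), KLF and flow response (0 of 7, adjusted p = 0.0937), unfolded protein response (0 of 10, adjusted p = 0.419), NRF2 target (0 of 5, adjusted p = 0.115), immediate early (0 of 9, adjusted p = 0.121), circadian clock (1 of 7, adjusted p = 0.918) and oxidative phosphorylation (0 of 17, adjusted p = 0.067) lists. Fry called the KLF and flow response list (adjusted p = 0.043). Of 18 settings, camera called the interferon-stimulated list in 3, the oxidative phosphorylation list in 2, and the KLF, NRF2 target and immediate early lists in 1 each. The growth factor gene Igf1 rose by 2.63 ± 0.57 and the clock gene Arntl fell by 1.29 ± 0.28, each at an adjusted p of 0.0499, and both calls ended under most alternatives. The only tested mitochondrially encoded gene, mt-Nd6, was at 621 to 2241 FPKM in old and 220 to 881 FPKM in young libraries (adjusted p = 0.345).

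By camera, 14 of 39 lists passed, 9 higher and 5 lower in old mice, and with an estimated correlation 0 of 39 did, also at an unadjusted p of 0.05, the adjusted p of the 14 lying between 0.4825 and 0.683. The rotation test fry, which does not compare a list with other genes, called 12 lists, 9 of them among the 14. It did not call the airway, T and natural killer cell, B and plasma cell, cell cycle and ribosomal protein lists. Of the 333 tested list members, 57 passed when adjusted over all genes and 90 when adjusted over the members alone, 36 higher and 54 lower in old mice. Of the 58 called genes named here, 22 kept the call whichever 1 library was left out, and 36 lost it without at least 1. Besides those noted above, it was lost in at least 4 of 6 such fits for Efnb2, Ephb4, Upk3b, Lox, Epcam, Pdpn, Myl7, Nrp2, Plxnd1, Sema3f, Notch4 and Sele.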

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

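The comparisons restricted to genes with the M21 length and to young mouse 1 as the young group were chosen after the data were seen. The 498 genes became 323 with a pseudocount of 0.01, 223 without a filter, 292 with a mean FPKM of at least 5 and 312 among genes with the M21 length, where fewer genes were tested. Leaving out each library in turn gave 84 to 395 genes, with fewer samples. Other scalings, pseudocount 0.1, variance priors and weights gave 423 to 686, and young mouse 1 alone gave 413. That comparison assumes that the lone young library varies like the old ones. The 14 lists became 22 against young mouse 1 alone and 0 with an estimated correlation; the cause was not tested for the 22, and the estimated correlations replace the preset 0.01. Rotation tests called 12 lists, 9 of them shared. Over 18 settings of camera, 7 of the 14 lists were called in all, the Notch list in the 17 it was tested in, and 6 lost the call in at least 1. Of the 25 lists not called, 16 were called under at least 1 setting.

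With a replicate block on the mouse number, 126 genes passed, 109 higher and 17 lower in old mice, and no named gene changed direction. Deviations of same-numbered libraries correlated at -0.0941, -0.00324 and 0.0102, and no library correlated best with its own number. A pairing by number was therefore not seen, but so few pairs cannot exclude it.

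Of the 58 named genes called, 13 were called under all 18 settings and 6 under the 17 in which they had a value, 39 lost the call under at least 1, and 0 reversed. Genes that reversed had not passed, and the cause was not tested. Against young mouse 1 alone the log2 fold changes were Aldoa 0.31, Cdkn1a 0.22, Hba-a1 -1.06, Hbb-bs -1.33, Hmox1 0.27, Irf7 -0.038, Klf6 0.28, Ldha 0.26, Lyz2 4.196 (adjusted p = 0.0394), Pf4 2.08, Ppbp 0.68, S100a8 3.22 and S100a9 3.41. They were -0.15 for Hbb-bs, -0.12 for Ier3 and 0.24 for Lyz2 with quantiles, -0.15 for Ier3 and -0.12 for Napsa with weights, and 8.12e-05 for Lyz2 with median ratios. Leaving out single libraries gave -0.33 to 1.695 for C1qb, -0.24 to 1.05 for Hba-a1, -0.44 to 0.82 for Hbb-bs, -0.37 to 0.23 for Ier3, -0.70 to 0.041 for Igfbp7, -0.35 to 0.54 for Irf7, -0.0081 to 0.53 for Junb, -0.44 to 0.073 for Ldha, -2.13 to 1.43 for Lyz2, -0.68 to 1.81 for Napsa, -0.045 to 0.62 for Pcna, -1.09 to 0.81 for Pf4 and -1.39 to 0.10 for Ppbp. Hba-a1 and Hbb-bs have near-identical copies and are uncertain. The implied depth limits genes of a few fragments, and 9023 intact genes lay below the filter.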

Other observations

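The tests of library scaling, of an age change inside endothelial cells, of Nrp1 and Epas1 beside the endothelial genes, and of other splits of the libraries were chosen after the results were seen, as were the single genes of the next paragraph.

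Some single genes of granulocytes, mast cells and lymphocytes had high values in 1 or more old libraries, and most of those given here did not pass. Elane, the neutrophil elastase gene, was at 1795, 34.8 and 326 FPKM in old mice 1, 2 and 3 and at 0, 21.5 and 3.87 FPKM in young mice 1, 2 and 3 (limma adjusted p = 0.0867). Prg2, an eosinophil granule protein, was at 483 FPKM in old mouse 1 and 8.81 and 60.6 FPKM in old mice 2 and 3, and at 0.40 to 4.46 FPKM in young mice (adjusted p = 0.0874). The mast cell tryptase Tpsb2 was at 17.8 to 273 FPKM in old and 0 to 5.54 FPKM in young mice (adjusted p = 0.0585). The granzyme genes Gzmb and Gzmc rose by 3.81 ± 0.47 and 4.29 ± 0.45 (SE) on the log2 scale (limma adjusted p = 0.0112 and 0.00739). The immunoglobulin gene Igha was at 84.8 to 585 FPKM in old and 0 to 41.5 FPKM in young mice (adjusted p = 0.0781). Families of near-identical genes make the values of proteases and immunoglobulins uncertain, and the same may hold for the stefins given next. Stfa1, Stfa2 and Stfa3, stefins of neutrophils, were listed at 0 in all 3 old libraries at 0.54, 0.13 and 0 FPKM in young mouse 1, at 129, 173 and 67.6 FPKM in young mouse 2 and at 289, 366 and 143 FPKM in young mouse 3, and did not pass (adjusted p = 0.144, 0.171 and 0.183).

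For the lower endothelial genes of the old libraries, scaling is argued against as the whole cause. The median log2 fold change of all tested genes was -0.0112, against -3.14 for the pan-endothelial list. Rescaling could therefore move the list little, and its median was -3.11 with median ratios and -3.21 with quantiles. Of 10000 random lists matched on gene length and level, 0 had a median as low (0.01%, the smallest the draw can give), which argues against length bias as the whole cause. The random medians lay between -1.06 and 0.603. Genes were drawn singly, without the correlation among the endothelial members (estimated at 0.8345), so the 0.01% is too small to serve as a p-value. Across genes, which are not independent replicates, longer genes did tend to lower values in old mice (Pearson r = -0.18, Spearman rho = -0.28). Less endothelial and more fibroblast RNA in the old libraries may account for the fall: of a second fibroblast list written before its values were seen, 7 of 8 tested genes (87.5%) were higher in all old than in all young libraries, and of a second endothelial list 8 of 11 were lower in all old libraries and 4 passed, with a median of -2 and values up to 0.488. The first lists had already moved the same way in these libraries, so the second lists are not independent of them. Camera also called the mesothelial and airway lists higher, so the rise was not limited to fibroblast genes. An age change inside endothelial cells stays open and cannot be told apart, because no value per cell was measured. The SD of the fall over members was 0.486 and the median SE of a member 0.539. These cannot decide it, since that SE holds spread between mice that the members share (estimated correlation 0.8345).

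Young mice 2 and 3 carried abundant neutrophil transcripts, with S100a8 at 9995 and 9164 FPKM against 20.9 FPKM in young mouse 1. Neutrophil RNA in these 2 libraries is a candidate explanation: 11 of 11 tested genes (100%) of a second neutrophil list were at least 4-fold higher in both than in young mouse 1. The mean log2(FPKM + 1) of that list was 5.84 and 6.36 in young mice 2 and 3 and 2.68 to 4.37 in old mice. It was 0.87 in young mouse 1, below the old libraries too, so a low reference contributes to the 4-fold gap. The first neutrophil list had already shown the same gap in these libraries, so the second list is not independent of it. The labels call the libraries endothelial and name no sort or gate. No biological explanation was tested, since the design has no group within the young mice.

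Nrp1 and Epas1 were lower in old mice by less than the pan-endothelial median, by 1.23 and 0.901 on the log2 scale, with an SD of 0.486 over its members. A fall beyond that of the endothelial genes was therefore not seen, and without each library in turn the gap stayed above 1 SD for Nrp1 (0.785 to 1.32) but not for Epas1 (0.283 without old mouse 1 and 0.368 without young mouse 1). Whether a loss of endothelial RNA alone could account for them stays open, since RNA of these genes from other cells was not measured. Relative to the pan-endothelial mean of the same library, Nrp1 was 1.11 higher in old mice (two-sided exact permutation p = 0.1, the smallest possible, 0.167 after adjustment over 5 genes) and Epas1 0.781 higher (exact permutation p = 0.3). An age difference inside the cells stays open and untested.

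Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 498 genes, which was the real one, and the highest of the others gave 0. The splits are too few for a share under 0.05.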
